A study of Xenopus tropicalis with 2 samples.

How the data were processed

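The series profiled genome occupancy in wild-type Xenopus tropicalis tadpole tail at 0 hours post amputation. It held 2 libraries made from genomic DNA, 1 from cells that were not sorted and 1 from cells passed through a fluorescence-activated cell sorter (FACS). Per the labels, tail tissue was dissociated with the enzyme blend Liberase. The protocol text that mentions sorting is the same for both libraries, so the group of each library was taken from its own FACS label. The labels did not name the assay within the class of genome occupancy profiling, nor the fluorescent population, if any, that was gated.

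The deposited table held raw counts of reads per peak, as whole numbers, in 1 column per library. Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, Bowtie, SAMtools, MACS2 and featureCounts, with no versions named and no order given. The peak names in the deposited table describe 1 merged set, so both libraries were counted over the same peaks. Which library or libraries each peak was called from, the handling of duplicate reads and of reads that map to several places, and any shift of read ends are not given in the sources used here. A merged set counted in both libraries cannot show peaks gained or lost as calls, only differences of read number within it. Every one of the peaks with a position was 400 bp wide, counted from the first to the last base given in the file, so peak width was not used as a class.

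The genome build is not given in the sources used here. The last peak on chromosome 1 ended at base 194891458, while the gene table at hand, of assembly UCB_Xtro_10.0, held a gene ending at base 217419418 of that chromosome. The builds were therefore treated as different, and no peak was assigned to a gene, promoter or other annotated feature. Gene lists for cell types and stress responses that were fixed before the data were examined, promoter classes and GC content were not analysed here. All positions are those of the deposited table.

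The table held 124349 peaks, of which 93635 lay on the 10 chromosomes, 30166 on 3706 scaffolds or unplaced sequences, and 548 had no position. Peaks without a position took 0.0924% of the unsorted and 0.0899% of the sorted reads, and stayed in the library totals. Among the rest, 1825 neighbouring pairs overlapped, so some reads could count for both members of a pair. The lowest number of reads summed over both libraries was 4, so peaks absent from both did not occur.

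Each library was scaled by its total of reads in peaks. The log2 ratio of a peak was the scaled sorted count over the scaled unsorted count, with a prior count of 0.5 added to each. A peak was counted as differing when it had at least 20 reads summed over both libraries, differed at least 2-fold, and had a 95% interval that excluded an equal level. Intervals of ratios came from the exact Clopper-Pearson interval of the share of a peak's reads in the sorted library, and those of shares of a library were Clopper-Pearson intervals of the share itself. With 1 library per group there was no residual degree of freedom, so no test between conditions was run and no p-value is given. The intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

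The number of differing peaks that counting error alone gives was obtained by drawing each peak's summed reads anew at the library shares, 100 times, and 20 times at each of the other minimums. On simulated counts for all 124349 peaks with 50 changed peaks per class, the rule found between 94% and 100% of 4-fold changes in the right direction. It found between 34.7% and 66% of 2-fold changes, since those lie on the threshold. Between 2.34% and 2.41% of the unchanged peaks passed the rule by counting error.

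The rule for items named in the text was fixed before the data were examined. Since genes could not be assigned, it named by position, among peaks with at least 100 summed reads, the 10 highest and the 10 lowest by the interval bound nearest to 0, and the 10 peaks with the most reads. A window of chromosome 3 was named as well, and was chosen after its values were seen.

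Alternatives fixed beforehand were TMM factors, DESeq2 size factors, scaling by the 5000 peaks with the most reads, a loess correction of the log2 ratio on mean log2 CPM with a span of 0.3, other read minimums, folds, interval levels and prior counts, and thinning of the deeper library. The window scan, the correlation of neighbouring peaks, the distance to chromosome ends, the chromosome-only counts and the scalings applied to shares, single chromosomes included, were chosen after seeing the data. Windows were 250 kb long with at least 20 peaks, and were compared with 100 permutations of chromosome peaks within bins of similar coverage. The scan of pooled reads was also compared with 100 permutations of blocks of 5, 10 and 20 consecutive peaks, which keep the correlation of neighbours.

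Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Scaling factors came from edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, which were used for nothing else.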

Results

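Genome occupancy was profiled in tail tissue of wild-type Xenopus tropicalis tadpoles, a frog whose larvae regrow an amputated tail. Both libraries came from tissue labelled 0 hours post amputation. In 1 library the dissociated cells had not been sorted, and in the other they had passed through a cell sorter. The comparison asks whether a profile made from sorted cells differs from one made without sorting. The unsorted library held 3176954 reads in peaks and the sorted library 3111092, a ratio of 1.02. The median peak had 15 reads in the unsorted and 16 in the sorted library. Only 4 peaks in the unsorted and 3 in the sorted library had no read, and a count of 0 allows a level of up to 0.944 and 0.964 CPM (reads scaled to a common library total), respectively. There were no replicates, so no difference described here could be set against the spread between animals or preparations.

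The profiles of both libraries correlated across peaks. Among peaks with at least 20 summed reads, most of the spread of the ratios was within reach of counting error, which is large at this depth. Across the 124349 peaks, log2 CPM correlated with a Pearson's r of 0.82 and a Spearman's rho of 0.704. Counting error alone gave a Pearson's r of 0.858, with a range of 0.857 to 0.86 over 100 draws, and a Spearman's rho of 0.754. Across the 9167 peaks with at least 100 summed reads, Pearson's r was 0.921 and Spearman's rho 0.82. Across the 93635 chromosome peaks they were lower, at 0.749 and 0.625. These are correlations across peaks, which are not replicates. Among the 105380 peaks with at least 20 summed reads, 91.7% lay within 2-fold of an equal level, where counting error alone gave 95.1%. The standard deviation of their log2 ratios was 0.57, against 0.49 from counting error. Counting error thus made up 73.6% of the variance, and the part beyond it had a standard deviation of 0.29. That share belongs to this depth, since the median peak of the whole set had 30 summed reads. The peaks with at least 100 reads had a standard deviation of 0.37, for which no value from counting error is given here.

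At the level of single peaks, 5464 of these 105380 (5.19%) differed at least 2-fold, 3725 of them higher and 1739 lower in the sorted library. Counting error alone gave a mean of 1287 higher peaks, with a maximum of 1363, and a mean of 1312 lower peaks, with a maximum of 1390. Well covered peaks stood further from that background. Of the 27966 peaks with at least 50 reads, 404 were higher and 273 lower, against 70.7 and 68.7 from counting error. Of the 9167 with at least 100 reads, 36 were higher and 40 lower, against 0.65 and 0.5. Peaks on the chromosomes supplied 3151 of the higher and 1191 of the lower peaks, which is 4.06% and 1.53% of the 77674 examined there. Those on scaffolds supplied 574 higher and 548 lower peaks, which is 2.07% and 1.98% of 27706. Chromosome peaks were shallower, with a median of 28 summed reads over all of them against 41 on scaffolds. Counting error was not computed for each place, so these percentages do not show that more peaks truly differed on chromosomes. The balance between directions depended on scaling. The higher peaks made up 68.2% of the differing peaks with library totals, 54.9% with TMM factors, 62.9% with DESeq2 size factors, 87.9% with scaling by the 5000 most covered peaks and 48.5% after the loess correction.

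The peak furthest above an equal level lay on chromosome 8 at 39010498 to 39010897. It had 17 unsorted and 104 sorted reads, which is 6.1-fold higher in the sorted library (log2 ratio 2.61, 95% interval 1.90 to 3.48). The 7 other peaks within 50 kb of it had a median log2 ratio of -0.27, so the difference stood alone in its surroundings. A deeper peak at 266553 to 266952 of scaffold_199 had 177 unsorted and 549 sorted reads (log2 ratio 1.66, 1.42 to 1.92). The peak on chromosome 4 at 14321421 to 14321820 had 32 and 92 reads (1.54, 0.96 to 2.18). Near the end of chromosome 1, the peak at 191629679 to 191630078 had 70 and 175 reads (1.35, 0.94 to 1.77). On chromosome 2, the peak at 143615889 to 143616288 had 41 and 104 reads (1.36, 0.84 to 1.93). The remaining 5 of the 10 highest peaks had log2 ratios from 1.07 to 1.18. They began at 8097421 and 109679732 of chromosome 8, 118137583 of chromosome 3, 5038 of scaffold_1815 and 301475 of scaffold_203. Around the peak on scaffold_1815, all 6 other peaks within 50 kb were also above 0, with a median log2 ratio of 0.70.

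Among the 10 lowest peaks, the best covered on a chromosome lay on chromosome 6 at 4982374 to 4982773. It had 403 unsorted and 153 sorted reads, which is 2.57-fold lower after sorting (log2 ratio -1.36, -1.65 to -1.10). The peak on chromosome 2 at 8242268 to 8242667 had 97 and 28 reads (-1.74, -2.42 to -1.14). The peak on chromosome 7 at 111004659 to 111005058 had 253 and 93 reads (-1.41, -1.77 to -1.07). On chromosome 4, the peak at 2121000 to 2121399 had 89 and 27 reads (-1.67, -2.37 to -1.06). On chromosome 3, the peak at 121221518 to 121221917 had 88 and 27 reads (-1.66, -2.35 to -1.04). The peak on chromosome 8 at 97626011 to 97626410 had 134 and 48 reads (-1.44, -1.96 to -0.97). The others began at 1088534 of chromosome 2, 93944677 of chromosome 1, 128076004 of chromosome 3 and 156 of scaffold_4443, with log2 ratios from -1.52 to -1.15. Each of these 20 peaks kept its side of 0 under the 3 other scalings, the loess correction and a prior count of 5. Those scalings move all log2 ratios alike, by at most 0.16, and the peaks were chosen for lying far from 0. No side could therefore change under them. The peak on scaffold_4443 fell under 2-fold with scaling by the 5000 most covered peaks (-0.99) and with the loess correction (-0.97).

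**Figure D1:**
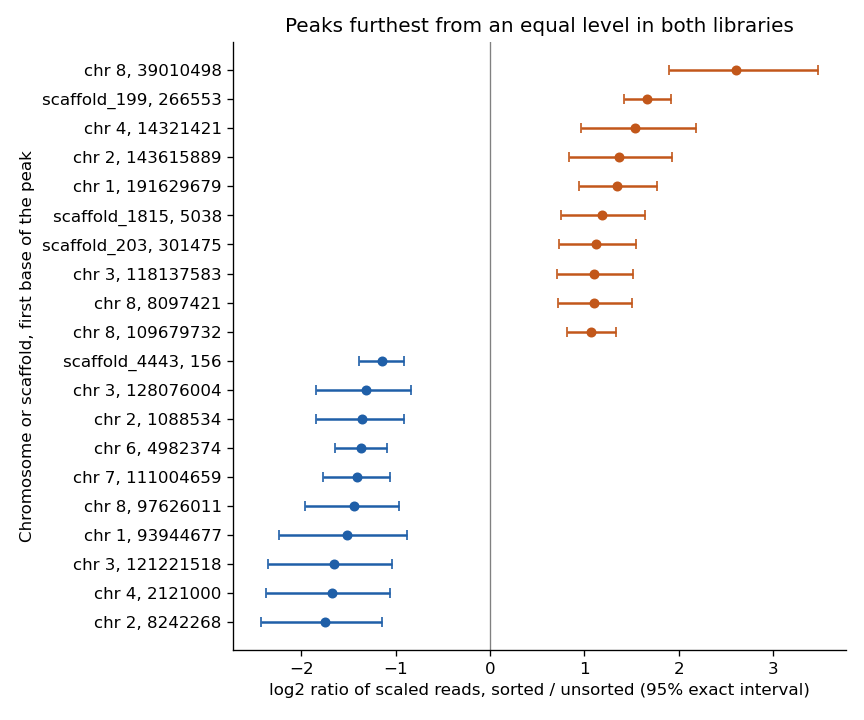
The log2 ratio of scaled reads, sorted over unsorted, for the 10 highest and 10 lowest peaks among those with at least 100 reads, labelled by chromosome or scaffold and first base. Bars are 95% exact intervals for counting error with 1 library per group, and the values run from -1.74 on chromosome 2 to 2.61 on chromosome 8.

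The most heavily covered peaks took a smaller share of the reads in the sorted library. The pair with the most reads lay on chromosome 6 at 69212583 to 69212982, with 17632 unsorted and 11336 sorted reads, and on chromosome 2 at 155184502 to 155184901, with 15970 and 10701. Their log2 ratios were -0.61 (-0.64 to -0.57) and -0.55 (-0.58 to -0.51). The other 8 of the 10 most covered peaks lay on scaffolds. The lowest of them, at 2607 to 3006 of scaffold_4722, had 5856 and 3190 reads (-0.85, -0.91 to -0.78). All 10 had intervals below 0 with library totals, although 6 of them came out above 0 after the loess correction, which removes the trend with coverage. Together the 10 peaks took 1.98% of the unsorted and 1.41% of the sorted reads. The 1000 most covered peaks took 16.3% of the unsorted and 14.0% of the sorted reads, a log2 share ratio of -0.22 (-0.22 to -0.21). Scaling by the 5000 most covered peaks, a set that holds these 1000, put their reads at -0.060 and left their shares unchanged. Without the first 10 of the 1000 peaks the log2 share ratio was -0.18.

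From about 50 reads upwards the share ratio declined with coverage, on chromosomes and on scaffolds. In the planned quintiles of coverage over all peaks, the log2 share ratio was 0.086, 0.095, 0.11, 0.10 and -0.081 from the lowest to the highest. The finer classes that follow were not planned. On the chromosomes, the log2 share ratio went up from 0.095 in peaks with under 20 reads to 0.14 (0.13 to 0.14) in those with 30 to 49 reads. Those with at least 200 and under 400 reads had -0.096 and those with 1000 or more reads had -0.33 (-0.35 to -0.32). The last class held 51 peaks, and the 2 most covered gave 33602 of its 80351 unsorted and 22037 of its 62479 sorted reads. Its median log2 ratio of -0.11 lay above the -0.21 of chromosome peaks with at least 400 and under 1000 reads. The typical chromosome peak thus showed no further decline there. On scaffolds the log2 share ratio was 0.028 under 20 reads and 0.011 at 30 to 49 reads. It was -0.14 with at least 200 and under 400 reads, and -0.24 with 1000 or more. Below 400 reads, scaffold peaks lay under chromosome peaks of like coverage in every class. Scaffolds as a whole took 40.5% of the unsorted and 38.2% of the sorted reads, a log2 share ratio of -0.086 (-0.090 to -0.082). Without the 1000 most covered peaks, in scaffolds and totals alike, it was -0.084. Scaling by the 5000 most covered peaks moved all log2 ratios by 0.16. That put the scaffold reads at 0.072 but left their share of each library as it was.

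**Figure D2:**
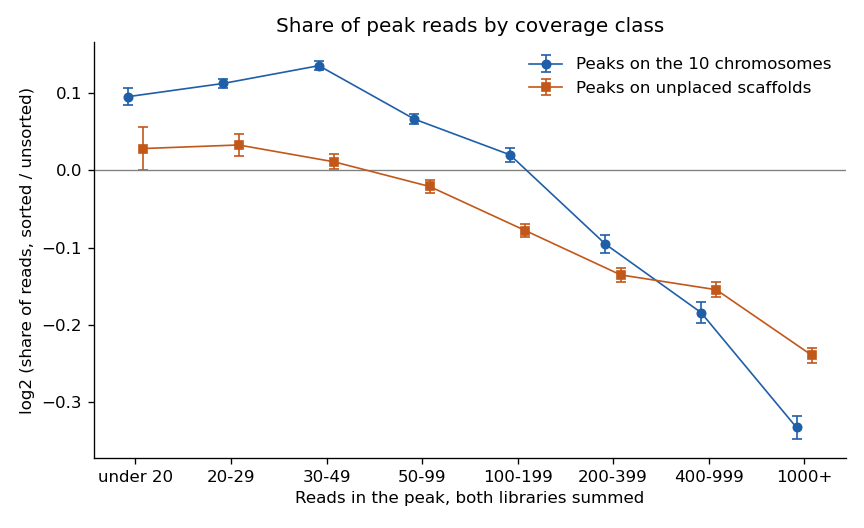
The log2 ratio of the share of reads, sorted over unsorted, for 8 classes of peak coverage, on the 10 chromosomes (circles) and on unplaced scaffolds (squares), with 95% exact intervals for counting error. Scaled by library totals, the chromosome points go up from 0.095 under 20 reads to 0.14 at 30 to 49 reads and then down to -0.33 at 1000 or more reads, and scaling by the 5000 most covered peaks would move every point by 0.16, which turns several signs. The last chromosome point pools 51 peaks whose median log2 ratio was -0.11, and 2 of them hold 33602 of its 80351 unsorted reads.

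Chromosomes differed in how far their share moved. Chromosome 3 took 5.79% of the unsorted and 6.40% of the sorted reads (log2 share ratio 0.14, 0.13 to 0.15). Of its 8231 peaks with at least 20 reads, 62.6% were above 0, against 58.1% of such peaks over all chromosomes. A peak with equal raw counts lies just above 0 after scaling. Chromosome 7 followed with 0.11, chromosome 4 with 0.091 and chromosome 1 with 0.086. On chromosomes 2, 8 and 10 the interval of the log2 share ratio included 0 with library totals. Chromosome 2 held 1 of the 2 most covered peaks, which gave 15970 of its 259617 unsorted and 10701 of its 255507 sorted reads. Chromosome 6 held the other. Shares of these chromosomes without those peaks were not computed, so their place in the order may rest on them. Each other scaling moves all chromosomes by 1 amount, so their order stays, but their level against 0 does not. Chromosome 3 had 0.077 with TMM factors, 0.11 with DESeq2 size factors and 0.30 with scaling by the 5000 most covered peaks. Chromosome 8 had -0.071, -0.034 and 0.15 in the same order, and chromosome 1 had 0.019, 0.056 and 0.24.

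Within chromosome 3, the window from 127750001 to 128000000 had the highest interval bound in a scan of pooled reads chosen after the data were seen. By its median log2 ratio of 0.47 it was not among the 14 windows that reached 0.50. Its 46 peaks held 2094 unsorted and 3166 sorted reads (log2 share ratio 0.63, 0.55 to 0.71), and 40 of them were above 0. In the last 80 kb, 27 of 29 peaks were above 0 and the pooled log2 ratio was 0.70 (0.61 to 0.79). In the middle, from 127830000 to 127920000, 8 of 9 peaks were above 0 and the ratio was 0.51 (0.24 to 0.79). The first 80 kb had 8 peaks and a ratio of 0.10 (-0.15 to 0.36). These parts were cut after the results were seen. Of the 17 peaks of the window with at least 100 reads, 13 had an interval above 0. The best covered, at 127945075 to 127945474, had 256 unsorted and 455 sorted reads (0.86, 0.64 to 1.09), and the peak at 127927079 to 127927478 had 71 and 141 (1.02, 0.60 to 1.45). The adjoining windows had log2 share ratios of 0.13 before and 0.14 after it. The second of these held the peak at 128076004 to 128076403, which was among the 10 lowest, with 123 and 48 reads.

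**Figure D3:**
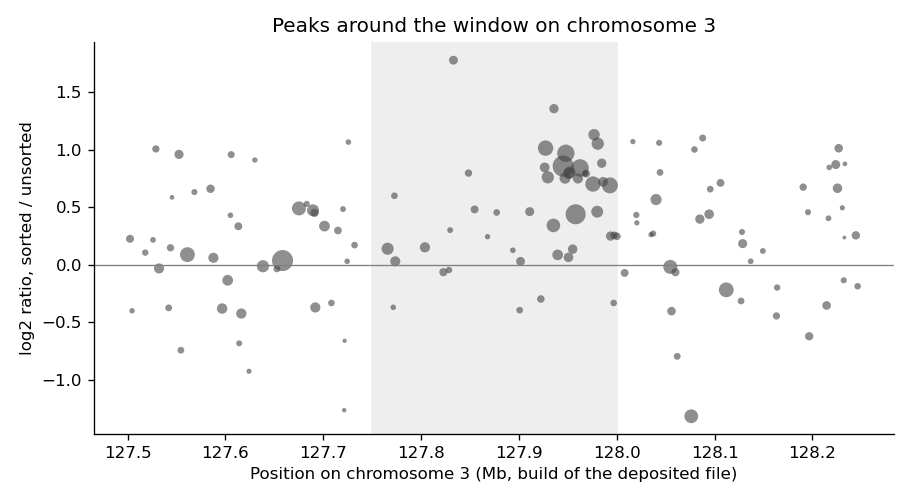
The log2 ratio, sorted over unsorted, of each peak between bases 127500001 and 128250000 of chromosome 3, against position in Mb; the area of a point grows with its reads up to a ceiling, and the window from 127750001 to 128000000 is shaded. Of the 29 peaks in the last 80 kb of the shaded window, 27 lie above 0, and the point at -1.32 to its right is the peak at 128076004.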

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

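The scalings of shares, of chromosomes and of the chromosome 3 window, the chromosome-only counts and the settings for neighbouring peaks were chosen only after the results were seen. Of the 150 values of the 30 named peaks under alternatives, 144 stayed on the same side of 0. This tally is no measure of stability for the 10 highest and 10 lowest peaks. They were chosen for lying far from 0, so the scalings could not turn them. The loess correction turned 6 of the most covered peaks, at scaffold_4409 (0.061), scaffold_2844 (0.044), scaffold_1674 (0.017), scaffold_937 (0.10), scaffold_2231 (0.095) and scaffold_5534 (0.17); it removes the trend with coverage by construction. Scaling by the 5000 most covered peaks gave 6452 higher and 887 lower peaks, and the loess correction 2407 higher. A minimum of 50 reads left 677 (404 higher, 273 lower) and one of 100 reads 76 (36 higher, 40 lower). Fewer peaks were examined, but the share that differed fell as well, from 5.19% at 20 reads to 2.42% and 0.83%. A 1.5-fold threshold gave 3043 lower peaks, and a 3-fold threshold 1221 (865 higher, 356 lower). The 99% interval gave 1918 (1340 higher, 578 lower) and a prior count of 5 gave 2940 (2083 higher, 857 lower), both stricter by construction. Across peaks, Pearson's r was 0.823 with at least 20 reads and 0.86 with a prior count of 5, and Spearman's rho 0.656 with at least 20 reads. The log2 ratio of scaffold reads was -0.15 with TMM factors, -0.12 with DESeq2 size factors and 0.072, so above 0, with scaling by the 5000 most covered peaks. That of the 1000 most covered peaks was -0.28, -0.25 and -0.060 in the same order. Shares within each library do not depend on these scalings. Without the 1000 most covered peaks, in scaffolds and totals alike, the scaffold log2 share ratio was -0.084. The chromosome 3 window had 0.78 with scaling by the 5000 most covered peaks and 0.48 without its 10 most covered peaks. Peaks 1 to 3 kb apart correlated with r = 0.209 at a minimum of 50 reads. Each of the other scalings adds 1 constant to all log2 ratios, 0.16 for the 5000 most covered peaks. The changes of pooled log2 ratios under them, and of counts under the latter, follow by construction. A lower fold threshold can only add peaks and a higher one only remove them. Where no construction is named, the cause was not tested. TMM factors, DESeq2 size factors, no read minimum and thinning left the counts of differing peaks within 1.5 times. The alternatives for promoter distance, gene lists and marker lists, GC matching included, were not run, since peaks could not be assigned to genes. No paired analysis was possible because each group held 1 library. Depth limits single peaks: counting error alone gave a mean of 2607 differing peaks at a minimum of 20 reads, against 5464 observed, and 1.15 at 100 reads, against 76.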

Other observations

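All tests of explanations in this part were chosen only after the results were seen, since none was planned for these patterns. Sorted reads were also spread unevenly along chromosomes. Peaks within 5 Mb of the outermost peak of a chromosome had a log2 share ratio of -0.037 (-0.043 to -0.031), against 0.11 (0.10 to 0.11) for those 20 to 40 Mb away. The mean log2 ratios per peak were 0.026 ± 0.0047 (SE across peaks, which are not replicates) and 0.12 ± 0.0042, and after the loess correction -0.067 ± 0.0047 and 0.017 ± 0.0042, so most of the difference between these means stayed. In the scan by window medians, 14 of 1640 windows reached a median log2 ratio of 0.50, against at most 12 in 100 permutations, and 12 windows had a median of -0.30 or less, against at most 11. The highest median of 0.64 lay below the highest permuted one of 0.84. Those permutations moved single peaks and so did not keep the correlation of neighbours.

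Reads were less concentrated in the most covered peaks of the sorted library. A few peaks taking most of the reads were not the whole cause with library totals, since the 1000 most covered peaks without the first 10 still had a log2 share ratio of -0.18. The share that these peaks took of each library does not depend on the scaling. Scaling by the 5000 most covered peaks adds 0.16 to every log2 ratio, which would bring that value near 0. Those 5000 include the 1000, so this shift towards 0 is by construction. It leaves the differences between coverage classes unchanged. Sequence shared among unplaced scaffolds alone was not the whole cause either with library totals, since chromosome peaks with at least 200 and under 1000 reads had -0.13. The same other scaling would put that value above 0, but would not change its distance from the other coverage classes. Sequence that chromosomes share with scaffolds or with one another stays open, since the handling of reads that map to several places is not given. A lower enrichment of peaks over background after sorting may lie behind the trend, which reached -0.27 in peaks with 1000 or more reads. Reads outside peaks were not analysed here, so this cannot be told apart from a difference in the cells themselves.

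Peaks near one another moved together. The log2 ratios of neighbours less than 1 kb apart correlated with r = 0.115, those 1 to 3 kb apart with 0.0915 (0.209 at a minimum of 50 reads), and those 30 to 100 kb apart with 0.0202, where the highest of 100 permutations was 0.0267. Peaks 200 places apart had 0.0109, and 0.0103 after the loess correction, on either side of their highest permuted value of 0.0105. Reads shared by adjacent peaks were not the whole cause, since 0.0915 at 1 to 3 kb exceeded the highest permuted value of 0.029, and neither was the coverage trend, since r was 0.0884 after the loess correction. A difference in cell types or cell state between the libraries could give such a pattern, and with 1 library per group it cannot be told apart from a difference between preparations.

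The chromosome 3 window from 127750001 to 128000000 was higher in the sorted library, with a lower bound of 0.50 for its log2 ratio without its most covered peak. Chance among many windows stays open: with blocks of 5, 10 and 20 consecutive peaks permuted, which keeps neighbours together, 2, 4 and 11 of 100 permutations gave a bound as high, up to 0.63. A few peaks were not the whole cause, since the ratio without its 10 most covered peaks was 0.48 (0.36 to 0.59). A single gain of DNA across the whole window stays open. The first 80 kb had 0.10 (-0.15 to 0.36) against 0.68 (0.60 to 0.77) in the rest. That cut was chosen after the results were seen and falls between a peak at 0.30 and one at 1.78. Its place favoured a difference between the parts, so the difference cannot decide the question. The spread among the window's peaks, at 2.00 times counting error, lay below the 95th percentile of windows, 2.27, as such a gain would allow. A shorter gain was not tested, and a cluster of sites more occupied in the sorted cells may also account for the window.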
